A study of Xenopus tropicalis with 16 samples.

How the data were processed

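Gene expression was measured in whole embryos and larvae of Xenopus (Silurana) tropicalis at NF stages 2, 16, 34 and 46, with 4 biological replicates per stage. Per the labels' protocols, total RNA was extracted with TRIzol, purified on RNeasy columns and labelled with Cy3 for a 1-colour Agilent array. How many embryos entered a sample is not given in the sources used here. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1, which gave 1 intensity on a linear scale per spot with its background subtracted (the processed signal), beside the median signal, the median local background and flags. The deposited table of the authors' processed values is on a log2 scale. Its columns correlated at r of 0.994 or more with log2 signals of their own array and 0.982 or less with any other, across spots, which are not independent replicates. How the authors adjusted these values between arrays stays unknown, and their centring and scale were not tested beyond this. Medians of its columns, replicates 1 to 4, were NF 2 6.81, 6.86, 6.83, 6.86, NF 16 7.01, 7.05, 6.99, 7.01, NF 34 7.04, 6.97, 7.04, 6.99 and NF 46 7.03, 7.05, 7.07, 7.05. The table was used only as an alternative.

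Each array held 45220 spots, of which 43803 were not controls and measured 32899 probes. Each of the 4 slides held 1 array of every stage, each stage took every position once, and each slide had 1 scan, so the slide could be fitted as a block and comparisons made within each slide. Slides are numbered 1 to 4 in the order of their codes in the headers. No spot was saturated, and 410 spots marked as outliers over all arrays were left out. Log2 of the processed signal minus the 75th percentile of its array was averaged over repeated spots. Arrays give no counts, so the number of arrays limits the precision.

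Probe accessions were named, without versions, through a RefSeq gene table of assembly UCB_Xtro_10.0. Of the probes, 15304 carry a RefSeq accession and 5891 matched, for 5617 genes; 1019 of these probes have only a LOC number and are not named in the text, and the other 17595 probes carry other accessions. The headers give the build as JGI 4.1, so no coordinates are printed. By the array's design 15119 probes, 1532 of them named, can bind other transcripts. For a gene with several probes the one with the highest mean signal is given, and opposite calls of another probe are stated. A change at the limit has each array under the mark at the higher of that array's lowest signal well above background and the probe's own.

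Probes well above background on all 4 arrays of at least 1 stage were tested (26612, 4989 of them named). A linear model with a mean per stage was fitted over all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and NF 16 against NF 2, NF 34 against NF 16 and NF 46 against NF 34 were tested two-sided, with the moderated F test over the 4 stages. P-values were adjusted by Benjamini and Hochberg over all probes tested, and a probe was called under 0.05. Where no probe of a gene was well above background on any array of a stage, the fold is a lower bound. It sets the bright stage's mean against the dim stage's, each array at the higher of its lowest signal well above background and the probe's. It does not cover array spread. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R's data.table version 1.17.8 read files and drew plots.

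The 22 gene lists were fixed in advance: oocyte and germ plasm, cell cycle and DNA replication, mesoderm and endoderm specification, neural plate patterning, Hox genes, neural crest, neuronal differentiation and synapse, skeletal muscle, heart, blood with globins and vasculature, eye, liver and plasma proteins, pancreas with stomach and intestine, epidermis with cement gland and hatching, motile cilia, pronephric kidney, thyroid and steroid hormone axes, immune cells, extracellular matrix and cartilage, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation and cell stress. Camera (limma) with an estimated correlation, two-sided, was run on 19 lists with at least 5 tested members, a minimum chosen after the coverage was seen, in 57 tests adjusted together. Neural crest, heart and ribosomal proteins were too small. List pairs share up to 2 members, apob lying in both the liver and the intestine list.

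Named genes follow a rule fixed with them. For each comparison it takes the 8 largest rises and falls among called genes well above background on all arrays of both stages and changed the same way on all slides, the 5 largest lower bounds each way, up to 4 called members of each list by size, and reference genes, of which 1, eef1a1o, was found. For length the text keeps the first 5, 3 and 2 of these ranks. Some genes that this rule takes are not reported here. Genes detected at 1 stage only, the per-array values and the gene families were chosen after their values were seen.

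In simulated data 200 of 26612 probes were changed, 50 each by 1.5-fold, 2-fold, 4-fold and 8-fold. Over the 3 comparisons the fit recovered 1, 18, 41 and 48, then 0, 13, 38 and 48, then 1, 16, 40 and 48. The real data had more calls and so a laxer cut on unadjusted p. Camera was checked on 100 random lists of 12 genes, shifted by 2 log2 units in the real values: 71, 98 and 100 of them passed in the 3 comparisons, and 0, 13 and 77 with a shift of 1.

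Alternatives were quantile normalization, centring on the median, scaling to 6 of 10 spike-in probes, normexp (offset 50), the authors' values, other filters on dim probes, the slide, position or replicate number as a block, other variance models, thresholds and set tests, fits on 8 arrays and each array left out in turn. Normexp was run on median signals, since the files hold no mean signal. Overlaps of calls between successive steps share the arrays of the middle stage, so they are given beside independent lists, a split of those arrays and simulated unchanged groups. Late transcripts were probes well above background on all NF 46 arrays, on none of NF 16 replicates 1 to 3, and above the 75th percentile at NF 46.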

Results

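RNA of whole Xenopus tropicalis embryos and larvae was measured at 4 stages of the Nieuwkoop and Faber (NF) series, the standard staging of Xenopus development. NF 2 is an early cleavage embryo, NF 16 a neurula, NF 34 a tailbud embryo and NF 46 a tadpole at about the onset of feeding. Each stage had 4 biological replicates, which gave 16 arrays on 4 slides, and each slide held 1 array of every stage. Of 32899 probes, 26612 were well above background on all 4 arrays of at least 1 stage and were tested, and these covered 4751 named genes. The share of probes well above background was 67.0% ± 3.37 at NF 2, 74.1% ± 7.68 at NF 16, 77.8% ± 8.15 at NF 34 and 83.9% ± 4.55 at NF 46 (SD, n = 4). Levels are log2 signals minus the 75th percentile of their array, given as mean ± SD (n = 4), and values in brackets after a gene are log2 changes ± SE unless marked as folds. A gene was measured on an array where its probe was well above background, and the number of arrays is given where this held for only some. Such a change rests partly on signals under that mark, and a value at the limit, with these signals raised to the detection limit, is added where it differs. Genes are said to have risen or fallen where limma's moderated test gave an adjusted p under 0.05. Rises and falls of a gene list under another scaling follow where the larger number moved by over 1.5 times, either moved so by at least 2 genes, or the balance between them changed, and with normexp only for the last. These are by quantiles (quantile normalization), by the median, by spike-ins, with normexp, with raised spots (normexp on spots raised to 0 or more) or in the authors' values. Medians of a list are of log2 changes, with bounds where dim members are put at theirs.

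The study asked how genes are regulated through early development, so transcripts that differ among the stages come first. The cell cycle gene birc5 and the antiproliferative gene btg5.1 had their highest mean at NF 2, the patterning genes ventx2.2, szl and hoxb8 at NF 16, and krt62 and cyp7a1 at NF 46. By limma's moderated F test, 22945 of the 26612 probes (86.2%) differed among the 4 stages. Between their highest and lowest stage, 21374 of them spanned at least 2-fold and 5472 at least 16-fold. The highest mean was at NF 2, 16, 34 and 46 for 7612, 5644, 2862 and 6827 of these probes. The lowest was there for 10132, 4169, 2298 and 6346. These can turn with the scaling and were not counted under another.

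**Figure D1:**
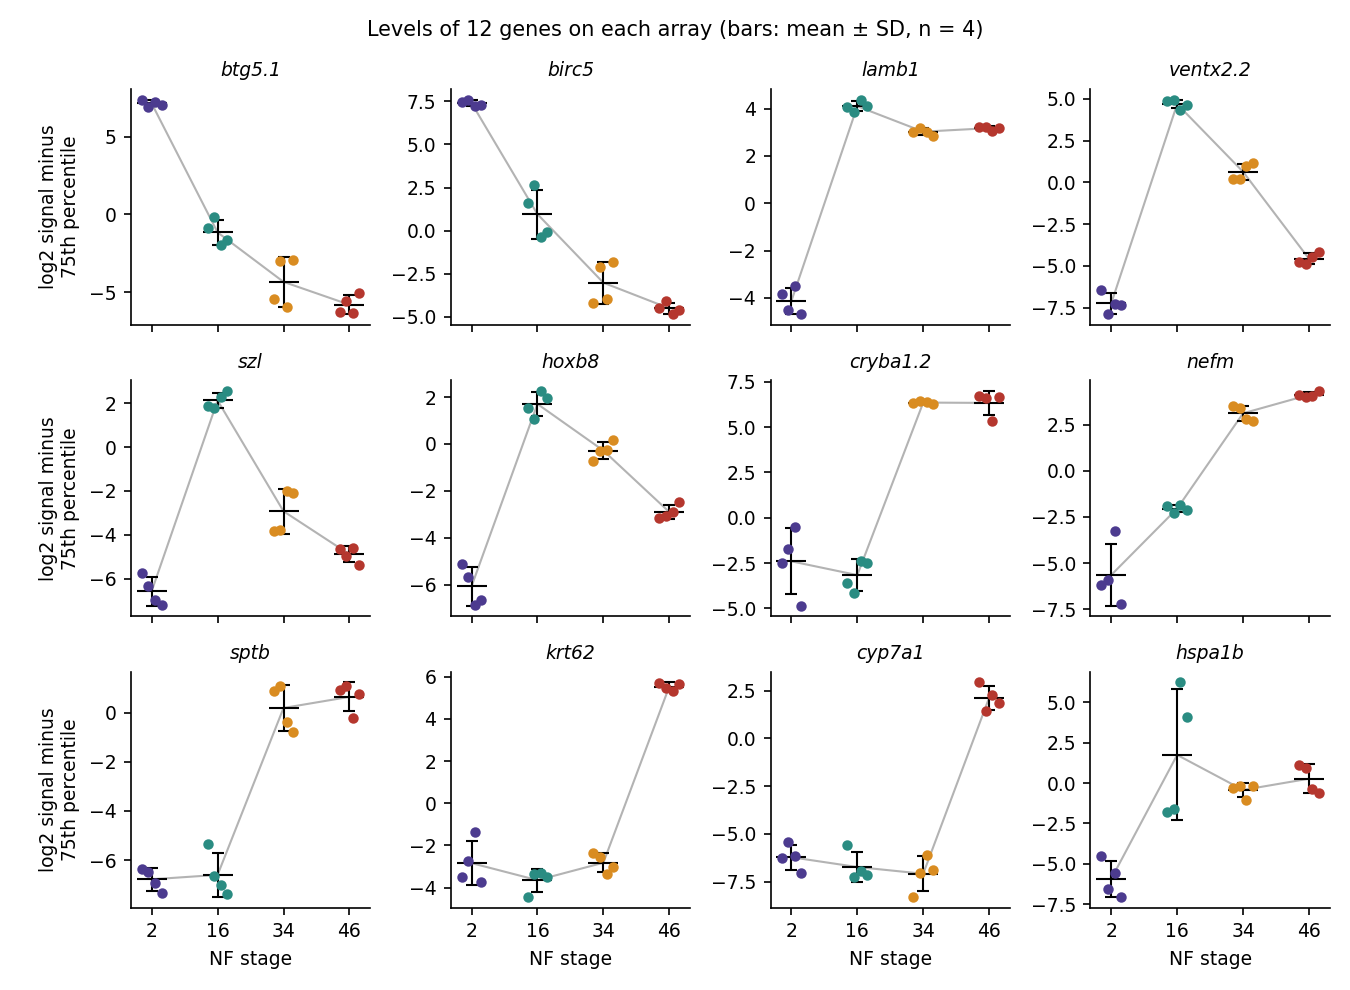
Levels of 12 genes on each array (log2 signal minus the 75th percentile of the array) against NF stage; points are the 4 arrays of a stage and bars the mean ± SD (n = 4). The NF 16 values of hspa1b, -1.79, -1.59, 6.23 and 4.12, lie apart, while ventx2.2 was at -7.25 ± 0.61 at NF 2 and 4.69 ± 0.26 at NF 16.

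Read over the 3 successive comparisons, 4205 probes were called in none, 2602 rose at the first only and 2225 fell at the first only. A rise and then a fall was seen for 1772 probes not called at the last step, a fall and then a rise for 1673, a second rise for 1472 and a fall at the second step only for 1392. Of directions over the 3 steps, there were 527 that rose and then fell, 3117 that fell and then rose, 2621 that rose at the first 2 steps and 208 that fell at the second step only scaled to the spike-ins. By quantile normalization and in the authors' values 1561 and 1562 rose at the first step only, and with normexp there were 13505 called at no step, 1020 that rose and then fell, 822 that fell and then rose and 571 that rose at the first 2 steps. Of the probes higher at NF 16 than at NF 2, 2995 were lower at NF 34, against 2415 for independent lists. With the NF 16 arrays split these were 2598 and 1936. Simulated groups shared 0.05 on average, but with no probe changed they cannot test overlap. At the 2 later steps 1824 probes rose at both, against 1117 for independent lists, and 2099 fell at both, against 1224. With the NF 34 arrays split these were 2060 against 1077 and 1948 against 947.

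**Figure D2:**
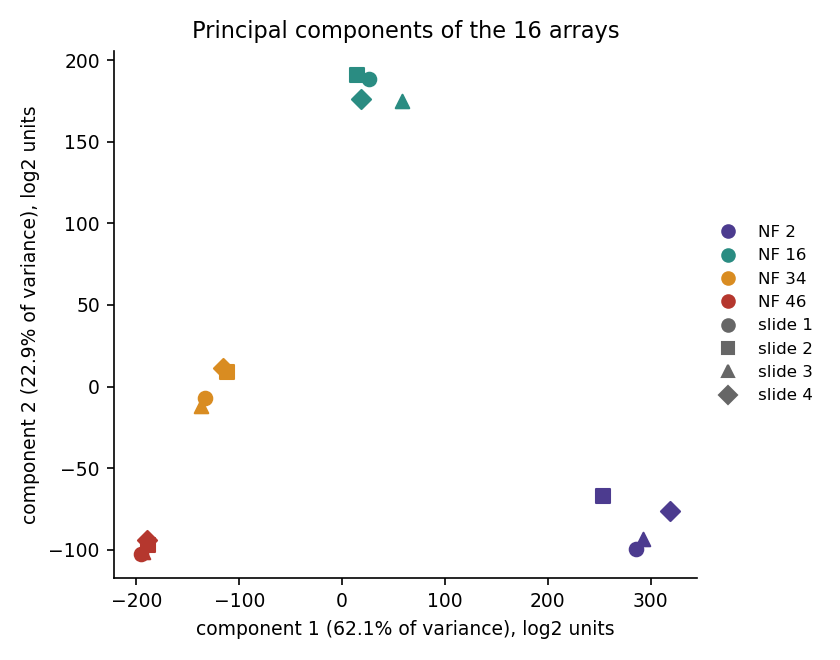
The 16 arrays on the first 2 principal components of the tested probes (log2 units), with colours for stages and symbols for slides. The components hold 62.1% and 22.9% of the variance.

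A few genes were well above background at a single stage. At NF 46 these included cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.14 ± 0.64), the secreted nuclease gene dnase1 (-2.43 ± 0.50) and the chemokine receptor gene ackr4 (-2.87 ± 0.36). At NF 16 they were admp, a BMP-family signal of the organizer (2.11 ± 0.43), lysmd2, myom2 and acod1la, and at NF 2 mapk14, gpr63 and ccny. Probes well above background on all 4 arrays of 1 stage and on no other array numbered 11 at NF 2, 18 at NF 16, 0 at NF 34 and 120 at NF 46, and 16318 were well above background on all 16 arrays. With the flag of a positive and significant signal in place of well above background, they numbered 0 at NF 2, 0 at NF 16, 0 at NF 34 and 12 at NF 46. With 1 array left out, the NF 2 number was 18 without NF 2 replicate 1 and 33 without NF 16 replicate 2, the NF 16 number was 28 without NF 16 replicate 1, the NF 34 number was 1 without NF 34 replicate 2 and 2 without NF 34 replicate 3 and the NF 46 number was 418 without NF 34 replicate 1.

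The comparison of NF 16 with NF 2 asks what changes between cleavage and the neurula. Levels of lamb1, a laminin subunit of basement membranes, rose from -4.13 ± 0.56 to 4.10 ± 0.22 (log2 change 8.23 ± 0.23, adjusted p = 1.30e-13). Those of the sodium pump subunit gene atp1b2 rose from -1.55 ± 0.85 to 6.64 ± 0.18 (log2 change 8.19 ± 0.31, adjusted p = 2.68e-12). The BTG-family gene btg5.1 fell from 7.14 ± 0.20 to -1.16 ± 0.82 (log2 change -8.30 ± 0.61, adjusted p = 7.15e-09). Levels of birc5, a chromosomal passenger protein of dividing cells, fell from 7.40 ± 0.17 to 0.96 ± 1.43 (log2 change -6.44 ± 0.61, adjusted p = 1.53e-07). The homeobox gene ventx2.2, a ventral patterning factor, was not well above background at NF 2 and was at least 2359-fold higher at NF 16 (adjusted p = 5.98e-14).

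Other large rises were of the activin receptor gene acvr1b (7.48 ± 0.30), of ube2v1 (7.46 ± 0.29) and of msmb.1 (7.32 ± 0.33), while c3ar1 (at least 1219.9-fold higher) and ceacam19lx (at least 1192-fold higher) were not well above background at NF 2. Falls included the oocyte linker histone gene h1-8 (-5.65 ± 0.65), wasll (-5.41 ± 0.25) and the Nodal co-receptor gene tdgf1.1 (-4.74 ± 0.49). Not well above background at NF 16 were the kinase genes mapk14 (at least 67.3-fold lower) and map3k20 (at least 66.4-fold lower) and the receptor gene gpr63 (at least 20.6-fold lower).

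The list for mesoderm and endoderm specification had 6 rises and 0 falls in 7 genes (median 4.92, 4.72 with bounds, 4.26 to 6.22 within slides; camera adjusted p = 0.285). They included the presomitic mesoderm factor msgn1 (at least 951-fold higher) and szl (at least 359-fold higher), a secreted regulator of BMP signalling. Neural plate patterning had 14 rises and 2 falls in 20 genes, but 14 and 4 by quantiles and by the median and 14 and 5 in the authors' values (median 3.11, 2.80 with bounds, 2.69 to 3.55 within slides; camera adjusted p = 0.248). Among these were dbx1 (at least 94.1-fold higher) and, of the midbrain-hindbrain boundary, en2 (6.62 ± 0.26, 6.34 at the limit, on 1 of 4 NF 2 arrays). The Hox list, whose genes set position along the body axis, had 11 rises and 1 fall in 14 genes (median 3.67, 3.58 with bounds, 2.86 to 5.09 within slides; camera adjusted p = 0.387). Changed members included hoxc4 (at least 544-fold higher) and hoxb8 (at least 209.7-fold higher). The neural crest list had 2 rises and 1 fall in 4 genes, but 1 and 1 by quantiles and 2 and 2 by the median and in the authors' values. Examples were sox8 (8.0 ± 0.25, 7.68 at the limit, on 1 of 4 NF 2 arrays) and tfap2b (1.69 ± 0.41). Oocyte and germ plasm had 1 rise and 7 falls in 9 genes (median -2.46, -2.33 to -1.36 within slides; camera adjusted p = 0.332). They included h1-8 and the oocyte growth factor gene bmp15 (-5.48 ± 0.46, -5.36 at the limit, on 2 of 4 NF 16 arrays). Cell cycle and DNA replication had 1 rise and 10 falls in 16 genes (median -1.54, -1.57 to -1.16 within slides; camera adjusted p = 0.212). Among these were birc5 and the kinesin gene kif2c (-2.85 ± 0.25).

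Skeletal muscle had 9 rises and 0 falls in 13 genes, but 7 and 1 by the median and in the authors' values (median 1.27, 1.01 to 2.33 within slides; camera adjusted p = 0.387). Called genes included the acetylcholine receptor gene chrna1 (7.93 ± 0.56, 7.68 at the limit, on 2 of 4 NF 2 arrays) and xirp1 (at least 73.3-fold higher). The heart list had 2 rises and 0 falls in 4 genes, the homeobox gene nkx2-3 (5.11 ± 0.30) and the myosin gene myh6 (2.96 ± 0.93, on 2 of 4 NF 2 arrays). Without NF 2 replicate 4 the change of myh6 was 1.79 (adjusted p = 0.0248). Motile cilia had 7 rises and 2 falls in 12 genes, but 7 and 4 by the median and in the authors' values (median 1.44, 1.11 to 1.76 within slides; camera adjusted p = 0.389). Examples were the dynein genes dnai2 (6.31 ± 0.31, 6.13 at the limit, on 3 of 4 NF 2 arrays) and dnah7 (5.61 ± 0.37, on 1 of 4 NF 2 arrays). Extracellular matrix and cartilage had 12 rises and 2 falls in 24 genes, but 9 and 5 by quantiles (median 0.96, 0.95 with bounds, 0.20 to 1.95 within slides; camera adjusted p = 0.415). They included lamb1 and the matrix proteoglycan gene vcan (at least 47.0-fold higher). The neuronal list had 5 rises and 0 falls in 9 genes, but 3 and 0 by quantiles and in the authors' values (median 0.83, 0.27 to 1.40 within slides; camera adjusted p = 0.510). Among these were the cytoskeletal genes map1b (3.66 ± 0.42, on 2 of 4 NF 2 arrays) and nefm (3.60 ± 0.56, 3.37 at the limit, on 1 of 4 NF 2 arrays). Pronephric kidney had 9 rises and 3 falls in 18 genes, but 8 and 5 by quantiles and in the authors' values (median 0.65, 0.20 with bounds, 0.12 to 1.27 within slides; camera adjusted p = 0.517). Changed members included the endocytic receptor gene lrp2 (8.201 ± 0.28, 7.78 at the limit, on 1 of 4 NF 2 arrays) and ggact (at least 73.7-fold higher). Cell stress had 8 rises and 1 fall in 13 genes (median 2.08, 0.94 to 2.32 within slides; camera adjusted p = 0.387). Examples were the early response gene junb (at least 25.2-fold higher) and the heat shock gene hspa1b (at least 206-fold higher), which without NF 16 replicates 1 to 4 in turn was at least 465-fold, 444-fold, 72.8-fold and 119-fold higher. On NF 16 replicates 1 to 4, hspa1b was at -1.79, -1.59, 6.23 and 4.12 and hspa8 at 4.86, 4.57, 6.86 and 7.27. On the same arrays the mean of the list, as deviations from each gene's mean over all arrays, was 0.17, 0.077, 1.11 and 0.90 for cell stress and 1.25, 1.52, 0.38 and 0.54 for oocyte and germ plasm. With 1 array left out, nefm changed by 4.38 without NF 2 replicate 3, chrna1 changed by 7.34 without NF 2 replicate 4 and myh6 changed by 3.97 without NF 2 replicate 3 and 1.79 without NF 2 replicate 4.

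The thyroid and steroid hormone list had 9 rises and 3 falls in 16 genes, but 5 and 4 by quantiles, 4 and 3 by the median and in the authors' values and 5 and 3 by spike-ins (camera adjusted p = 0.888). They included the deiodinase gene dio2 (3.28 ± 0.30, on 2 of 4 NF 2 arrays) and the retinoid receptor gene rxrg (-3.27 ± 0.42, -3.02 at the limit, on 1 of 4 NF 16 arrays). Liver and plasma proteins had 6 rises and 3 falls in 17 genes (camera adjusted p = 0.888). Among these were the complement gene c5 (9.09 ± 0.23, 8.83 at the limit, on 1 of 4 NF 2 arrays) and the kininogen gene kng1 (at least 39.4-fold higher). The eye list had 5 rises and 0 falls in 17 genes, but 3 and 3 by quantiles and in the authors' values, 4 and 2 by the median and 3 and 0 with raised spots (camera adjusted p = 0.802). They included rhodopsin, rho (probe not specific, 8.35 ± 0.16, 8.31 at the limit, on 2 of 4 NF 2 arrays) and the crystallin gene cryba2 (3.97 ± 0.56). The blood and vessel list had 3 rises and 2 falls in 10 genes, but 1 and 2 by quantiles and in the authors' values, 2 and 2 by the median and with raised spots and 1 and 1 with normexp (camera adjusted p = 0.890). Examples were the granule enzyme gene mpo (8.04 ± 0.21, on 3 of 4 NF 2 arrays) and the VEGF receptor gene flt1 (1.31 ± 0.35, on 2 of 4 NF 2 arrays). Immune cells had 3 rises and 2 falls in 10 genes, but 2 and 5 by quantiles, 1 and 1 with normexp and 2 and 3 in the authors' values (camera adjusted p = 0.999). They included laptm5 (-3.94 ± 0.17) and the chemokine receptor gene cxcr4 (3.19 ± 0.26). Epidermis, cement gland and hatching had 2 rises and 1 fall in 6 genes (camera adjusted p = 0.802). Among these were the desmosomal plakin gene ppl (9.54 ± 0.60, 9.50 at the limit, on 2 of 4 NF 2 arrays) and grhl1 (-2.12 ± 0.23). Ribosomal proteins had 1 rise and 1 fall in 2 genes, but 0 and 1 by quantiles, with normexp and in the authors' values, the fall being of rps19 (-2.17 ± 0.17), and oxidative phosphorylation had 0 rises and 1 fall in 5 genes (camera adjusted p = 0.936), with the fall in ndufs6 (-1.14 ± 0.17). With 1 array left out, cryba2 changed by 4.63 without NF 2 replicate 3 and ppl changed by 10.25 without NF 2 replicate 3 and 8.78 without NF 2 replicate 4.

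Pancreas, stomach and intestine had 4 rises and 4 falls in 12 genes, but 3 and 4 by quantiles, 3 and 5 by the median and in the authors' values, 4 and 3 by spike-ins and with raised spots and 2 and 1 with normexp (camera adjusted p = 0.999). Falls included those of the apolipoprotein gene apob (-3.72 ± 0.94, -3.46 at the limit, on 3 of 4 NF 2 and 1 of 4 NF 16 arrays) and the digestive enzyme gene cpa1 (-3.31 ± 0.75, -3.21 at the limit, on 2 of 4 NF 16 arrays). On NF 2 replicates 1 to 4, apob was at -4.73, -0.86, 0.33 and -4.20 and cpa1 at -1.55, -1.31, 0.28 and -3.84. With 1 array left out, apob changed by -4.51 without NF 2 replicate 1, -2.83 without NF 2 replicate 3 and -4.33 without NF 2 replicate 4 and cpa1 changed by -2.69 without NF 2 replicate 3, -4.06 without NF 2 replicate 4 and -3.93 without NF 16 replicate 4. Of 197 probes bright at NF 46 and dark on NF 16 replicates 1 to 3, 11.2%, 42.6%, 48.2% and 9.14% were well above background on NF 2 replicates 1 to 4. In the heart, epidermis, neuronal and muscle lists the NF 2 values also spread, with myh6 at -4.75, -2.47, -0.77 and -7.33, ppl at -5.44, -4.42, -2.87 and -7.29, nefm at -6.18, -5.91, -3.29 and -7.19 and chrna1 at -6.31, -4.17, -3.63 and -7.09. Without NF 2 replicates 2 and 3 and NF 16 replicate 4, chosen after the values were seen, 7331 higher and 6531 lower were called for NF 16 against NF 2. The changes were then -2.10 for apob (adjusted p = 0.0128) and 5.12 for myh6 (adjusted p = 1.17e-05). They were 4.67 for nefm, 9.43 for chrna1, 4.72 for cryba2, 10.90 for ppl, 4.34 for map1b, 8.82 for atp1b2 and -5.02 for h1-8, all still called.

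For NF 16 against NF 2, 16763 probes were called in all, 9191 higher and 7572 lower, of which 7481 and 5606 changed at least 2-fold. Of named genes, 1607 were higher and 1382 lower. The split between higher and lower turned with the scaling, to 7019 higher and 9102 lower by quantile normalization, 7076 higher and 9575 lower centred on the median and 6800 higher and 9791 lower in the authors' values. Probes well above background on all 16 arrays gave 4861 higher and 6065 lower and probes that the array's design marks as specific, a choice made after seeing the data, 5076 higher and 3589 lower. Normexp gave 5034 higher and 4502 lower, and with it the larger of the 2 numbers of a list moved by over 1.5 times in 10 of the 22 lists. With the slide as a block 9786 higher and 7701 lower were called, and 93.1% of the calls went the same way on all 4 slides. Within slides 1 to 4, 9848 and 6214, 6885 and 6582, 8486 and 5679, 10412 and 5877 probes were at least 2-fold higher and lower. The lowest camera adjusted p with an estimated correlation was 0.212. The list for neural plate patterning had 0.0320 by quantile normalization and 0.0352 in the authors' values. Adjusted over the list alone, the numbers of rises and falls changed only for oocyte and germ plasm (1 and 8), Hox genes (12 and 1), neuronal differentiation and synapse (4 and 0), extracellular matrix and cartilage (12 and 1). Probes of atp1b2, acvr1b, ube2v1, h1-8, c3ar1, mapk14, kif2c, msgn1, tfap2b, chrna1, rho, cpa1, grhl1, ggact, laptm5, vcan, rps19, ndufs6 and eef1a1o can bind other transcripts by the array's design. By quantile normalization tfap2b and flt1 were no longer called (adjusted p = 0.0894 and 0.441), and in the authors' values flt1 was not called (adjusted p = 0.158). With normexp gpr63, tfap2b, flt1, apob, cpa1 and rxrg were not called (adjusted p = 0.108 to 0.549).

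**Figure D3:**
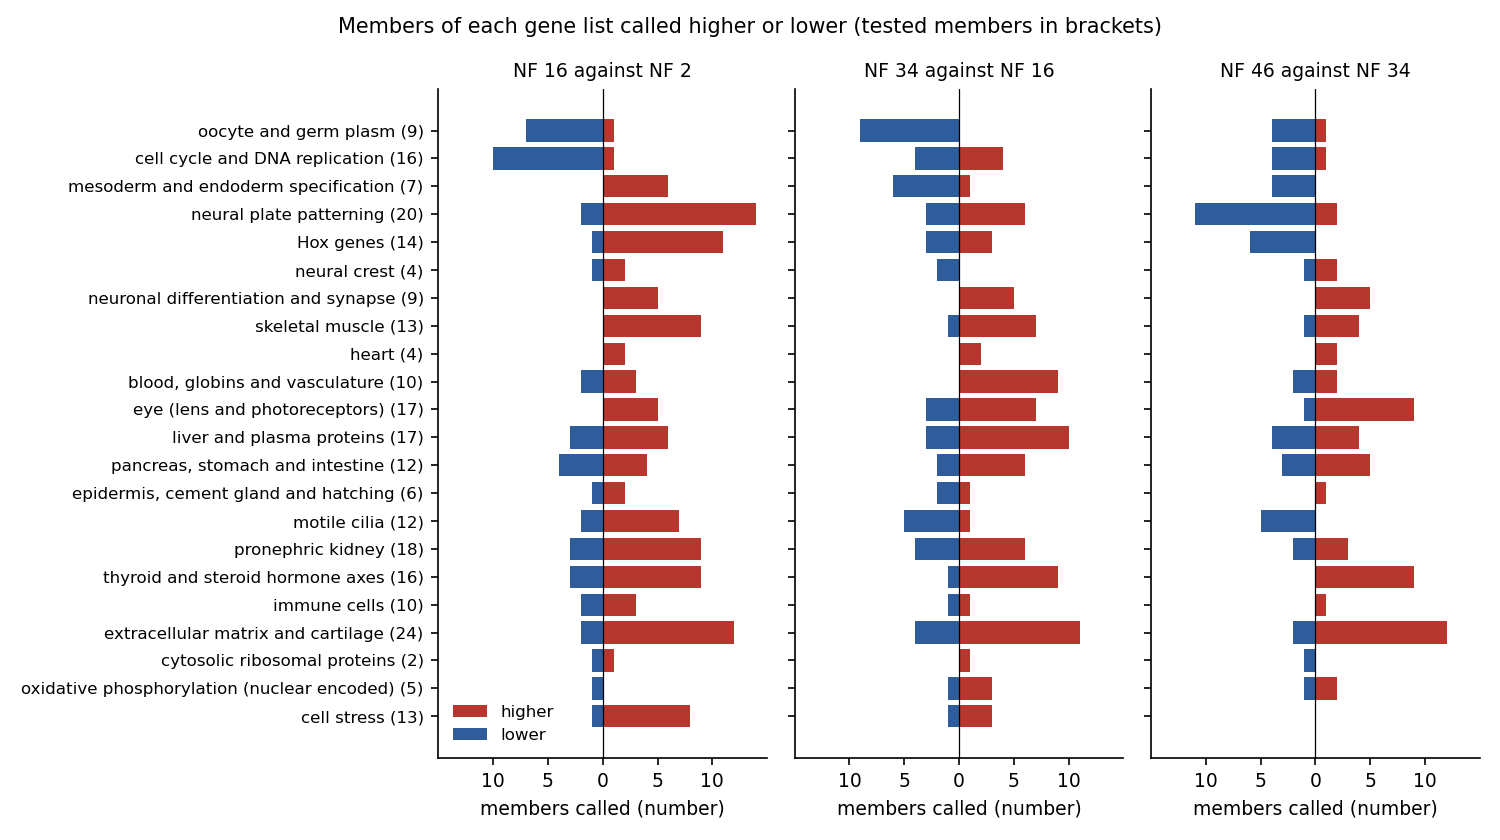
Numbers of members of the 22 gene lists called higher (right of 0) or lower (left of 0) in each comparison, with tested members in brackets. Mesoderm and endoderm specification had 6 rises and 0 falls in 7 genes at NF 16 and 1 rise and 6 falls in 7 genes at NF 34, and under another scaling the majority turned for blood and immune cells at NF 16, for eye, epidermis, cilia, kidney and hormone lists at NF 34, and for immune cells at NF 46.

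The comparison of NF 34 with NF 16 covers the way from neurula to tailbud embryo. The lens crystallin gene cryba1.2 rose from -3.17 ± 0.86 to 6.36 ± 0.053 (log2 change 9.53 ± 0.68, adjusted p = 1.94e-08), while the neurofilament gene nefm rose from -2.05 ± 0.19 to 3.11 ± 0.42 (log2 change 5.15 ± 0.56, adjusted p = 1.61e-06). The endoderm factor sox17b.2 fell from 2.56 ± 0.091 to -3.42 ± 0.31 (log2 change -5.98 ± 0.41, adjusted p = 1.39e-08), and szl fell from 2.12 ± 0.35 to -2.92 ± 1.03 (log2 change -5.05 ± 0.43, adjusted p = 1.38e-07). The organizer gene admp was not well above background at NF 34 and was at least 383-fold lower (adjusted p = 7.17e-10).

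Other large rises were of dgkq (8.83 ± 0.70), a diacylglycerol kinase gene, the collagen gene col6a1 (6.20 ± 0.46) and the plasminogen gene plg (4.92 ± 0.65). Not well above background at NF 16 were rab38 (at least 272-fold higher), the muscle filament gene des.2 (at least 135-fold higher) and cpxm1 (at least 94.4-fold higher). Falls included ceacam19lx (-5.77 ± 0.32), gatd3alb.1 (-5.03 ± 0.52) and msgn1 (-4.75 ± 0.37), while lysmd2 (at least 36.9-fold lower) and the homeobox gene mixer (at least 30.5-fold lower) were not well above background at NF 34. Without NF 16 replicate 2, lysmd2 was at least 24.6-fold lower.

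Mesoderm and endoderm specification had 1 rise and 6 falls in 7 genes (median -4.75, -4.69 to -2.87 within slides; camera adjusted p = 0.285), with sox17b.2 and szl among the falls. Oocyte and germ plasm had 0 rises and 9 falls in 9 genes, but 0 and 5 by spike-ins (median -2.63, -3.49 to -1.80 within slides; camera adjusted p = 0.219). Changed members included h1-8 (-4.31 ± 0.65, on 3 of 4 NF 34 arrays) and the cap-binding factor gene eif4e1b (-4.20 ± 0.26, on 3 of 4 NF 34 arrays). Cell cycle and DNA replication had 4 rises and 4 falls in 16 genes, but 7 and 2 by spike-ins and 2 and 3 with normexp (camera adjusted p = 0.933). Examples were birc5 (-3.98 ± 0.61, on 3 of 4 NF 34 arrays) and the licensing factor gene cdt1 (-2.40 ± 0.30). The Hox list had 3 rises and 3 falls in 14 genes, but 3 and 5 by quantiles, with raised spots and in the authors' values, 3 and 4 by the median, 5 and 2 by spike-ins and 0 and 3 with normexp (camera adjusted p = 0.933). They included hoxd13 (-4.18 ± 0.38) and hoxb8 (-1.98 ± 0.36). Neural plate patterning had 6 rises and 3 falls in 20 genes, but 6 and 5 by the median and 11 and 1 by spike-ins (camera adjusted p = 0.933). Among these were the proneural gene neurog3 (3.12 ± 0.22) and hes5.1 (at least 6.14-fold higher). The neural crest list had 0 rises and 2 falls in 4 genes, but 2 and 2 by spike-ins. The falls were of sox8 (-1.90 ± 0.25) and tfap2b (-1.90 ± 0.41, on 2 of 4 NF 34 arrays).

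The blood and vessel list had 9 rises and 0 falls in 10 genes (median 2.13, 1.87 with bounds, 1.58 to 2.74 within slides; camera adjusted p = 0.212). Called genes included the red cell spectrin gene sptb (at least 75.1-fold higher) and the erythropoietin receptor gene epor (at least 38.4-fold higher). Liver and plasma proteins had 10 rises and 3 falls in 17 genes, but 13 and 0 by spike-ins (median 1.31, 1.17 with bounds, 0.62 to 1.78 within slides; camera adjusted p = 0.387). Examples were apob (11.54 ± 0.94, 11.28 at the limit, on 1 of 4 NF 16 arrays) and the plasma protein gene itih2 (7.67 ± 0.71, on 1 of 4 NF 16 arrays). Skeletal muscle had 7 rises and 1 fall in 13 genes (median 1.19, 0.79 to 1.69 within slides; camera adjusted p = 0.517), with des.2 up and the sarcomere gene myom2 (at least 25.5-fold lower) down. The heart list had 2 rises and 0 falls in 4 genes, the troponin gene tnnt2 (at least 39.6-fold higher) and myh6 (4.04 ± 0.93). The neuronal list had 5 rises and 0 falls in 9 genes (camera adjusted p = 0.390). They included nefm and map1b (4.00 ± 0.42). Pancreas, stomach and intestine had 6 rises and 2 falls in 12 genes (camera adjusted p = 0.449). Among these were apob and cpa1 (10.73 ± 0.75, 10.62 at the limit, on 2 of 4 NF 16 arrays), and cpa1 changed by 11.35 without NF 16 replicate 4 and by 11.35 without the 3 arrays named above. Extracellular matrix and cartilage had 11 rises and 4 falls in 24 genes, but 15 and 1 by spike-ins (camera adjusted p = 0.460). Changed members included col6a1 and the matrix glycoprotein gene tnc (5.57 ± 0.35, on 3 of 4 NF 16 arrays).

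The eye list had 7 rises and 3 falls in 17 genes, but 10 and 1 by spike-ins, 1 and 2 with normexp and 1 and 4 with raised spots (camera adjusted p = 0.890). Examples were cryba2 (3.94 ± 0.56) and the lens filament gene bfsp1 (2.85 ± 0.66, 2.57 at the limit, on 1 of 4 NF 16 arrays). The hormone list had 9 rises and 1 fall in 16 genes, but 9 and 4 by the median, 11 and 0 by spike-ins, 0 and 1 with normexp and 6 and 4 with raised spots (camera adjusted p = 0.387). They included the nuclear receptor gene nr0b1 (4.34 ± 0.28, on 1 of 4 NF 16 arrays) and the prolactin receptor gene prlr (at least 6.23-fold higher). Pronephric kidney had 6 rises and 4 falls in 18 genes, but 10 and 2 by spike-ins, 1 and 2 with normexp and 3 and 4 with raised spots (camera adjusted p = 0.933). Among these were the cadherin gene cdh16 (2.73 ± 0.36) and the peptidase gene enpep (at least 4.37-fold higher, on 3 of 4 NF 34 arrays). Motile cilia had 1 rise and 5 falls in 12 genes, but 3 and 1 by spike-ins (camera adjusted p = 0.415). Called genes included mcidas (-2.12 ± 0.21), a regulator of multiciliated cells, and hydin (1.26 ± 0.19). Epidermis, cement gland and hatching had 1 rise and 2 falls in 6 genes, but 2 and 0 by spike-ins (camera adjusted p = 0.802). Examples were gata2 (1.83 ± 0.49, on 2 of 4 NF 16 arrays) and the astacin protease gene astl2a (-1.42 ± 0.28). Cell stress had 3 rises and 1 fall in 13 genes, but 6 and 0 by spike-ins (camera adjusted p = 0.936). They included the chaperone gene hspa5 (1.40 ± 0.20) and the heme oxygenase gene hmox1 (1.04 ± 0.32). Immune cells had 1 rise and 1 fall in 10 genes, but 5 and 0 by spike-ins and 0 and 1 with normexp (camera adjusted p = 0.987), with laptm5 (1.56 ± 0.17) and cxcr4 (-1.32 ± 0.26). Oxidative phosphorylation had 3 rises and 1 fall in 5 genes (median 0.89, 0.84 to 1.15 within slides; camera adjusted p = 0.655). Among these were ndufs6 (3.54 ± 0.17) and ndufs4 (-1.10 ± 0.22), of which another probe was called the other way. Ribosomal proteins had 1 rise and 0 falls in 2 genes, but 2 and 0 by spike-ins, the rise being of rps19 (0.57 ± 0.17).

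For NF 34 against NF 16, 13880 probes were called in all, 6887 higher and 6993 lower, of which 5348 and 4415 changed at least 2-fold. Of named genes, 1275 were higher and 1240 lower. Scaled to the spike-ins, 12931 higher and 1482 lower were called. Probes well above background on all 16 arrays gave 3740 higher and 5465 lower and probes that the array's design marks as specific, a choice made after seeing the data, 3736 higher and 3452 lower. Normexp gave 2839 higher and 3296 lower, and with it the larger of the 2 numbers of a list moved by over 1.5 times in 17 of the 22 lists. With the slide as a block there were 7012 higher and 7491 lower, and 95.6% of the calls went the same way on all 4 slides. Within slides 1 to 4, 6397 and 5113, 5240 and 4903, 6220 and 5628, 5705 and 6095 probes were at least 2-fold higher and lower. Leaving out the 3 arrays named above gave 6569 higher and 6556 lower. The lowest camera adjusted p was 0.212, for blood, globins and vasculature, which had 0.0269 by quantile normalization and 0.0352 in the authors' values. Adjusted over the list alone, the numbers changed only for skeletal muscle (8 and 2), pancreas, stomach and intestine (6 and 3), thyroid and steroid hormone axes (9 and 2), extracellular matrix and cartilage (11 and 5). Probes of dgkq, gatd3alb.1, msgn1, lysmd2, mixer, h1-8, eif4e1b, neurog3, hes5.1, hoxd13, tfap2b, myom2, cpa1, gata2, astl2a, hydin, cdh16, laptm5, rps19, ndufs6, ndufs4 and eef1a1o can bind other transcripts by the array's design. With normexp, hes5.1, bfsp1, gata2, enpep and prlr had changes of -0.22, -0.17, -0.37, -0.63 and -0.36, uncalled, and tfap2b, tnnt2, epor, hydin, nr0b1, laptm5, ndufs4 and hmox1 were not called (adjusted p = 0.0539 to 0.439). With its negative spots raised to 0 bfsp1, gata2, enpep and prlr were not called (adjusted p = 0.0834 to 0.257). Scaled to the spike-ins astl2a, cxcr4 and ndufs4 were not called (adjusted p = 0.272, 0.383 and 0.640).

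**Figure D4:**
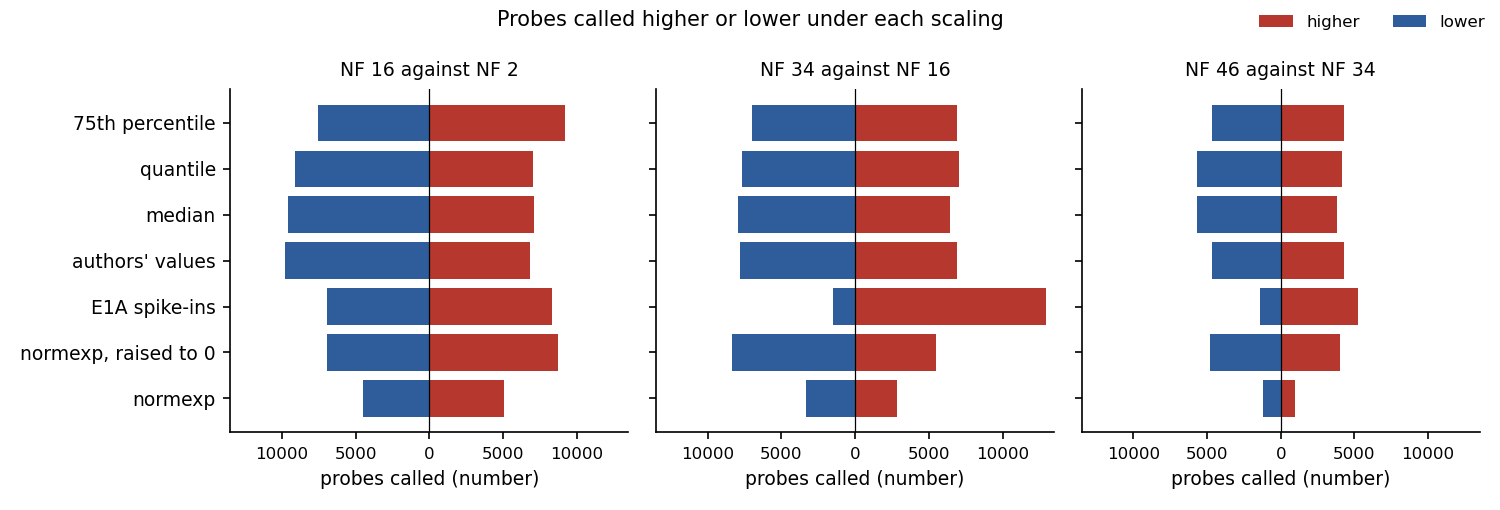
Numbers of probes called higher (right of 0) or lower (left of 0) in each comparison under 7 ways of scaling or correcting the arrays. At NF 34 against NF 16, 12931 higher and 1482 lower were called with spike-in scaling and 6887 higher and 6993 lower with the 75th percentile.

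The comparison of NF 46 with NF 34 follows the tailbud embryo to the tadpole. The keratin gene krt62 rose from -2.82 ± 0.44 to 5.54 ± 0.19 (log2 change 8.36 ± 0.42, adjusted p = 2.77e-09). Levels of fabp6, a bile acid binding protein of the ileum, rose from -0.75 ± 0.45 to 5.38 ± 0.22 (log2 change 6.13 ± 0.93, adjusted p = 1.24e-04). The bile acid enzyme gene cyp7a1 was not well above background at NF 34 and was at least 365-fold higher (adjusted p = 3.96e-09). Levels of ventx2.2 fell from 0.64 ± 0.49 to -4.58 ± 0.32 (log2 change -5.21 ± 0.30, adjusted p = 8.69e-09). Those of c8b, a terminal complement component, fell from 1.90 ± 0.22 to -2.44 ± 0.088 (log2 change -4.34 ± 0.23, adjusted p = 4.62e-09).

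Other large rises were of the carotenoid-cleaving enzyme gene bco1 (5.85 ± 0.39), rhagl (5.703 ± 0.33) and nufip1 (5.44 ± 0.27), while ttc27 (at least 1335-fold higher) and dnase1 (at least 14.8-fold higher) were not well above background at NF 34. Falls included crisp1.6 (-4.55 ± 0.42), msmb.1 (-4.37 ± 0.33) and the astacin protease gene astl2f (-3.76 ± 0.31). Not well above background at NF 46 were slc12a3l (at least 31.3-fold lower), the DNA repair gene fance (at least 15.4-fold lower) and astl2g (at least 8.40-fold lower).

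Pancreas, stomach and intestine had 5 rises and 3 falls in 12 genes, but 5 and 0 by spike-ins (median 1.29, 0.93 to 1.88 within slides; camera adjusted p = 0.415). Changed members included fabp6. The eye list had 9 rises and 1 fall in 17 genes (median 1.13, 0.82 to 1.05 within slides; camera adjusted p = 0.387). Examples were the photoreceptor genes prph2 (5.31 ± 0.36, on 3 of 4 NF 34 arrays) and rbp3 (4.45 ± 0.45, on 2 of 4 NF 34 arrays). The neuronal list had 5 rises and 0 falls in 9 genes (median 1.23, 0.91 to 1.37 within slides; camera adjusted p = 0.332). They included the glutamate receptor gene gria1 (4.997 ± 0.49, on 3 of 4 NF 34 arrays) and the neurofilament gene nefl (3.21 ± 0.25). The hormone list had 9 rises and 0 falls in 16 genes (median 0.74, 0.58 to 0.80 within slides; camera adjusted p = 0.332). Among these were the growth hormone gene gh1 (3.80 ± 0.49) and prlr (2.93 ± 0.31). Extracellular matrix and cartilage had 12 rises and 2 falls in 24 genes (median 1.13, 0.98 to 1.33 within slides; camera adjusted p = 0.351). Called genes included the collagen gene col12a1 (6.71 ± 0.39, on 1 of 4 NF 34 arrays) and the fibrillin gene fbn1 (4.51 ± 0.22, on 3 of 4 NF 34 arrays). Liver and plasma proteins had 4 rises and 4 falls in 17 genes, but 4 and 5 by the median, 6 and 2 by spike-ins, 2 and 1 with normexp, 6 and 4 with raised spots and 5 and 3 in the authors' values (median 0.58, -0.17 to 1.02 within slides; camera adjusted p = 0.936). Examples were cyp7a1 and the fibrinogen gene fgg (3.98 ± 0.56, 3.75 at the limit, on 2 of 4 NF 34 arrays).

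Neural plate patterning had 2 rises and 11 falls in 20 genes, but 2 and 6 by spike-ins (median -0.996, -1.06 to -0.91 within slides; camera adjusted p = 0.285). They included hes5.1 (3.26 ± 0.34) and the proneural gene neurog2 (-2.58 ± 0.30, -2.25 at the limit, on 1 of 4 NF 46 arrays). The Hox list had 0 rises and 6 falls in 14 genes, but 0 and 10 by quantiles and in the authors' values and 0 and 2 by spike-ins (median -0.69, -0.78 to -0.63 within slides; camera adjusted p = 0.449). Among these were hoxb8 (-2.62 ± 0.36) and hoxc11 (-1.58 ± 0.27). Mesoderm and endoderm specification had 0 rises and 4 falls in 7 genes (median -0.61, -0.49 with bounds, -1.31 to -0.56 within slides; camera adjusted p = 0.387). Changed members included msgn1 (-4.69 ± 0.37, on 2 of 4 NF 46 arrays) and szl (-1.96 ± 0.43, on 3 of 4 NF 46 arrays). Cell cycle and DNA replication had 1 rise and 4 falls in 16 genes, but 0 and 6 by the median and 1 and 1 by spike-ins (median -0.56, -0.64 to -0.54 within slides; camera adjusted p = 0.219). Examples were the replicative helicase gene mcm5 (-1.37 ± 0.22) and the condensin gene ncapd2 (-1.33 ± 0.29). Oocyte and germ plasm had 1 rise and 4 falls in 9 genes, but 1 and 2 by spike-ins (median -0.51, -0.22 with bounds, -0.75 to -0.24 within slides; camera adjusted p = 0.389). They included pgat (-4.54 ± 0.26, on 3 of 4 NF 46 arrays) and h1-8 (-2.52 ± 0.65, on 3 of 4 NF 34 and 1 of 4 NF 46 arrays). Motile cilia had 0 rises and 5 falls in 12 genes, but 0 and 3 by quantiles and 0 and 0 by spike-ins (median -0.38, -0.65 to -0.12 within slides; camera adjusted p = 0.338). Among these were cfap206 (-1.03 ± 0.22) and mns1 (-1.02 ± 0.16).

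Skeletal muscle had 4 rises and 1 fall in 13 genes, but 4 and 3 by the median (camera adjusted p = 0.890). Called genes included the parvalbumin gene pvalb (3.92 ± 0.37, on 1 of 4 NF 34 arrays) and des.2 (2.44 ± 0.52). The heart list had 2 rises and 0 falls in 4 genes, myh6 (2.97 ± 0.93) and tnnt2 (1.23 ± 0.40). The blood and vessel list had 2 rises and 2 falls in 10 genes, but 3 and 2 by spike-ins and with raised spots and 1 and 2 with normexp (median 0.43, -0.039 to 0.68 within slides; camera adjusted p = 0.999, with the direction down), with mpo (-2.49 ± 0.21) and the heme synthesis gene fech (-1.78 ± 0.22). Pronephric kidney had 3 rises and 2 falls in 18 genes, but 3 and 0 by spike-ins (camera adjusted p = 0.963). Examples were enpep (3.33 ± 0.38, on 3 of 4 NF 34 arrays) and the bicarbonate transporter gene slc4a4 (3.05 ± 0.47). The neural crest list had 2 rises and 1 fall in 4 genes, but 1 and 0 by quantiles and 0 and 0 with normexp. They included the melanosome gene pmel (1.59 ± 0.51) and sox8 (1.00 ± 0.25). Oxidative phosphorylation had 2 rises and 1 fall in 5 genes, but 1 and 1 with normexp (camera adjusted p = 0.888). Among these were cox7a1 (2.85 ± 0.35, 2.60 at the limit, on 1 of 4 NF 34 arrays) and ndufs4 (-1.49 ± 0.22). Epidermis, cement gland and hatching had 1 rise and 0 falls in 6 genes, but 0 and 0 by quantiles, by the median, with normexp, with raised spots and in the authors' values (camera adjusted p = 0.933), the rise being of grhl1 (0.68 ± 0.23). Immune cells had 1 rise and 0 falls in 10 genes, but 0 and 3 by quantiles, 0 and 1 by the median, 0 and 0 by spike-ins and with normexp, 1 and 1 with raised spots and 1 and 3 in the authors' values (camera adjusted p = 0.936), the rise being of laptm5 (0.47 ± 0.17). Ribosomal proteins had 0 rises and 1 fall in 2 genes, but 0 and 0 by spike-ins, the fall being of rps19 (-0.95 ± 0.17). Cell stress had 0 rises and 0 falls in 13 genes, but 0 and 2 by the median (camera adjusted p = 0.802), and hspa8 differed by -0.73 ± 0.56 (adjusted p = 0.356) and gadd45b by -0.71 ± 0.31 (adjusted p = 0.0946). The translation factor gene eef1a1o, used as a reference, differed by -0.43 ± 0.35 (adjusted p = 0.294) at the first step and -0.22 ± 0.35 (adjusted p = 0.628) at the second, and rose here by 1.45 ± 0.35 (adjusted p = 0.00432).

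For NF 46 against NF 34, 8974 probes were called in all, 4316 higher and 4658 lower, of which 3206 and 2207 changed at least 2-fold. Of named genes, 880 were higher and 768 lower. Scaled to the spike-ins, 5230 higher and 1429 lower were called. Probes well above background on all 16 arrays gave 1759 higher and 4004 lower and probes that the array's design marks as specific, a choice made after seeing the data, 2599 higher and 2068 lower. Normexp gave 967 higher and 1225 lower, and with it the larger of the 2 numbers of a list moved by over 1.5 times in 20 of the 22 lists. With the slide as a block there were 4528 higher and 4820 lower, and 98.8% of the calls went the same way on all 4 slides. Within slides 1 to 4, 3501 and 3007, 4434 and 3223, 3818 and 2274, 5004 and 3304 probes were at least 2-fold higher and lower. Leaving out the 3 arrays named above gave 4356 higher and 4612 lower. The lowest camera adjusted p was 0.219. Adjusted over the list alone, the numbers changed only for Hox genes (0 and 7), liver and plasma proteins (5 and 5), epidermis, cement gland and hatching (0 and 0), immune cells (0 and 0). Probes of nufip1, crisp1.6, ttc27, fance, h1-8, msgn1, hes5.1, pmel, gria1, fgg, grhl1, mns1, laptm5, rps19, ndufs4 and eef1a1o can bind other transcripts by the array's design. Scaled to the spike-ins, ncapd2, cfap206, mns1, laptm5 and rps19 were not called (adjusted p = 0.0770, 0.119, 0.0756, 0.0684 and 0.0716). By quantile normalization sox8, grhl1 and laptm5 were not called (adjusted p = 0.0911, 0.108 and 0.0572) and gadd45b was (0.00554). In the authors' values grhl1 was not called (adjusted p = 0.0742) and gadd45b was (0.0282). With normexp dnase1, fance, astl2g, h1-8, ncapd2, szl, neurog2, hoxc11, pmel, sox8, pvalb, tnnt2, fgg, grhl1, enpep, prlr, laptm5 and cox7a1 were not called (adjusted p = 0.0556 to 0.878), and with its negative spots raised to 0 h1-8 and grhl1 were not called (adjusted p = 0.152 and 0.0613).

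The call of grhl1 ended with the slide as a block (adjusted p = 0.0509) and that of laptm5 without the 3 arrays named above (0.0608). Leaving out single arrays ended calls of 5 genes, with limma's adjusted p in brackets. The call of grhl1 ended without NF 34 replicate 1 (0.0950), NF 34 replicate 2 (0.0646), NF 34 replicate 3 (0.0722), NF 46 replicate 2 (0.0511), NF 46 replicate 3 (0.0870) and NF 46 replicate 4 (0.0759). The call of laptm5 ended without NF 2 replicate 3 (0.0501), NF 16 replicate 2 (0.0512), NF 16 replicate 4 (0.0507), NF 34 replicate 1 (0.0773), NF 34 replicate 2 (0.120), NF 34 replicate 3 (0.0782), NF 34 replicate 4 (0.0554), NF 46 replicate 1 (0.101), NF 46 replicate 3 (0.0990) and NF 46 replicate 4 (0.0953). The call of myh6 ended without NF 34 replicate 3 (0.0582), NF 34 replicate 4 (0.0572) and NF 46 replicate 1 (0.0520). The call of pmel ended without NF 34 replicate 1 (0.0702), NF 34 replicate 2 (0.0678), NF 46 replicate 1 (0.0519) and NF 46 replicate 3 (0.0688). The call of tnnt2 ended without NF 34 replicate 3 (0.0862), NF 34 replicate 4 (0.0754), NF 46 replicate 1 (0.0570) and NF 46 replicate 2 (0.0739). The changes of grhl1, laptm5, pmel, myh6 and tnnt2 with any 1 array left out ranged from 0.58 to 0.80, 0.40 to 0.54, 1.37 to 1.87, 2.79 to 3.18 and 1.04 to 1.44, and gadd45b was called without NF 2 replicate 1 (adjusted p = 0.0323).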

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

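The tests of explanations in this part were all chosen after the results were seen. A value was picked out where the gap between the highest or lowest array of a stage and the nearest of the other 3, divided by the range of the 4, was above Dixon's critical value. Of 396 groups of 4 values, 20 were picked out (5.05%), against about 5% by chance. For gene levels these were 12 of 300, for list means 7 of 76 and for array measures 1 of 20.

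The gene levels (log2 signal minus the 75th percentile of the array) that lay apart from the other 3 arrays of their stage are given with the range of those 3. On NF 2 replicate 1 they were dnai2 (-6.01, others -4.43 to -4.13) and kng1 (-4.19, others -6.27 to -6.04). On NF 16 replicate 3 it was atp1b2 (6.37, others 6.72 to 6.75). On NF 34 replicate 1 it was cox7a1 (-5.78, others -6.45 to -6.36). On NF 34 replicate 4 it was mpo (4.91, others 4.19 to 4.29). On NF 46 replicate 1 they were cox7a1 (-2.91, others -3.61 to -3.51), fgg (-0.94, others -1.39 to -1.33), mns1 (0.63, others 0.98 to 1.04) and prph2 (0.89, others 1.07 to 1.096). On NF 46 replicate 2 it was laptm5 (-0.28, others 0.0014 to 0.045). On NF 46 replicate 3 they were hspa8 (6.58, others 5.596 to 5.74) and ncapd2 (-1.29, others -2.09 to -1.99).

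The list means that lay apart are given in the same way. On NF 2 replicate 1 they were oocyte and germ plasm (3.24, others 3.37 to 3.395), neural plate patterning (-1.66, others -2.21 to -2.16) and eye (lens and photoreceptors) (-0.96, others -1.65 to -1.61). On NF 2 replicate 2 it was motile cilia (-1.11, others -0.97 to -0.94). On NF 16 replicate 1 it was thyroid and steroid hormone axes (-0.59, others -0.67 to -0.67). On NF 16 replicate 2 it was liver and plasma proteins (-1.46, others -0.82 to -0.75). On NF 46 replicate 2 it was liver and plasma proteins (1.82, others 2.00 to 2.03). The mean log2 signal of the spike-ins on NF 2 replicate 4 was 14.92, against 15.21 to 15.26 on the other NF 2 arrays.

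Of the 197 probes of late transcripts, 11.2%, 42.6%, 48.2% and 9.14% were well above background on NF 2 replicates 1 to 4. A higher background on NF 2 replicates 2 and 3 is argued against, since the median of probes never above background was at most -7.60 there, and -6.23 and -7.23 on replicates 1 and 4. Transcripts present alike in all NF 2 embryos are argued against by replicate 4, where the median signal of the brightest 99, 50 and 20 of these probes at NF 46 was at most 0.181 times that on replicate 2, while on replicate 1, at 0.250%, 0.138% and 0.319% of the NF 46 level against 0.414%, 0.422% and 0.422% on replicate 2, this stays open. A small amount of later-stage RNA may be the source on replicates 2 and 3. Slopes of signal on NF 46 level were 0.335, 0.827, 0.984 and 0.257 on NF 2 replicates 1 to 4 (SE 0.0420, 0.0357, 0.0289 and 0.0310). NF 16 replicate 4 had 14.2% and a slope of 0.298 (SE 0.0377), but the other NF 16 arrays, dark by choice, give no comparison. A smaller trace stays open on arrays with lower slopes, and how it came there was not tested. Levels of the crygdl. genes, apob, cpa1, myh6, ppl, nefm, chrna1 and cryba2 at NF 2 and of cpa1 at NF 16 are read with this in mind.

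Splits of the same arrays that set the slides aside argue against chance as the source of the calls. For NF 16 against NF 2, 1 of the 35 splits of the 8 arrays, the real one, gave 16763 probes, and the highest other gave 4197. That split set NF 2 replicate 1 and NF 16 replicates 1, 3 and 4 against the rest. For NF 34 against NF 16, 1 of 35 splits gave 13880 and the highest other 5, and for NF 46 against NF 34 1 of 35 gave 8974 and the highest other 1. Of the splits, 8 in each comparison keep 1 array of every slide on each side, too few for a share under 0.05, and besides the real one these gave at most 0, 0 and 0 probes in the 3 comparisons. By limma's moderated F test, 1 of 100 drawn splits into 4 groups of 4, the real one, gave 22945 probes, and the highest other gave 6554. With 1 array of every slide in each group, 1 of 100 drawn splits, the real one, gave 22945 and the highest other 11326.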

How the results depend on the processing

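Which alternatives were tried was chosen before the data were examined, except normexp with negative spots raised to 0, the fit without NF 2 replicates 2 and 3 and NF 16 replicate 4, and the probes marked as specific alone, which were chosen after seeing the data. Apart from leaving out single arrays, named genes kept their call and its direction, or stayed uncalled, in 1270 recomputed values, lost the call in 59, gained it in 2 and reversed in 5. Gene lists gained a call in 66, lists too small to test moved by more than the spread between slides in 21, and in the other 705 none passed or none moved so far. Over these the median of a list had the other sign in 52. Of 396 list counts under other scalings, a number of rises or falls moved by over 1.5 times in 167, in 65 of them through 1 gene. Numbers of called probes stayed within 1.5 times in 138 and left that range in 50. The slide block, the position block, eBayes with trend and robust, fits on 8 arrays, the filter of 1 array and the stricter adjusted p for the F test moved no number of called probes outside that range. Signs of 28 of 66 list medians turned under some alternative, the largest of them 1.37. Median and direction by camera differed for muscle, blood and kidney at NF 46, pancreas and oxidative phosphorylation at NF 16 and cell stress at NF 34. Detection limits the folds of dim genes, as the share of probes well above background was 67.0% at NF 2 and 83.9% at NF 46.

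Scaling moved the median log2 change of all tested probes, given here in the order of the 3 comparisons (NF 16 against NF 2, NF 34 against NF 16 and NF 46 against NF 34). It was 0.33, -0.14 and -0.015 with the 75th percentile, -0.21, -0.14 and -0.13 by quantile normalization, -0.065, -0.23 and -0.13 centred on the median, 0.29, 0.81 and 0.28 scaled to the spike-ins and -0.23, -0.17 and -0.061 in the authors' values. It was 0.60, -0.57 and -0.050 with normexp, 0.32, -0.29 and -0.072 with its negative spots raised to 0 and 0.14, -0.15 and -0.015 without the 3 arrays. Changes relative to these shifts are what the scalings leave. Quantile normalization gave medians of 2.62 for neural plate patterning and 0.18 for neural crest at NF 16 against NF 2, a median of 2.09 for blood, globins and vasculature at NF 34 against NF 16 and a median of -0.71 for cytosolic ribosomal proteins at NF 46 against NF 34. Centring on the median gave medians of 0.25 for neural crest and -0.88 for cytosolic ribosomal proteins at NF 16 against NF 2 and a median of -0.65 for cytosolic ribosomal proteins at NF 46 against NF 34. Scaling to the spike-ins gave 12931 higher and 1482 lower at NF 34 against NF 16 and 1429 lower at NF 46 against NF 34. It gave medians of -0.0067 for neural crest, 3.13 for heart and 1.27 for cytosolic ribosomal proteins at NF 34 against NF 16 and medians of 0.65 for neural crest and -0.24 for cytosolic ribosomal proteins at NF 46 against NF 34. The authors' values gave medians of 2.73 for neural plate patterning, 0.20 for neural crest and -0.94 for cytosolic ribosomal proteins at NF 16 against NF 2 and a median of 2.16 for blood, globins and vasculature at NF 34 against NF 16. In directions over the 3 steps, there were 1561 that rose at the first step only by quantile normalization and 1562 that rose at the first step only in the authors' values. Scaled to the spike-ins there were 527 that rose and then fell, 3117 that fell and then rose, 2621 that rose at the first 2 steps and 208 that fell at the second step only. For these 4 the cause was not tested.

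Normexp with an offset of 50 gave 9536 called, 5034 higher and 4502 lower at NF 16 against NF 2, 6135 called, 2839 higher and 3296 lower at NF 34 against NF 16, 2192 called, 967 higher and 1225 lower at NF 46 against NF 34 and 15218 probes that differ among the 4 stages. In directions over the 3 steps there were 13505 called at no step, 1020 that rose and then fell, 822 that fell and then rose and 571 that rose at the first 2 steps. It also gave a median of 0.21 for neural crest at NF 16 against NF 2 and medians of 0.45 for heart and -0.016 for cytosolic ribosomal proteins at NF 34 against NF 16. Reversed changes were -0.22 for hes5.1, -0.17 for bfsp1, -0.37 for gata2, -0.63 for enpep and -0.36 for prlr at NF 34 against NF 16. For these counts and reversals the cause lies in the fit. On NF 2 replicate 4, NF 16 replicates 1 and 2, NF 34 replicate 4 and NF 46 replicate 1, 7, 7, 16, 3 and 2 spots had a median signal below their local background. The fitted backgrounds were -425, -328, -1089, -260.2 and -260.1 on these arrays, and 7.21, 20.8, 10.2, 35.5 and 19.8 with those spots raised to 0. On NF 34 replicate 3 and NF 46 replicate 2, 1 and 19 spots lay below by at most 7, and the fits were 18.6 and 5.74. With all of them raised to 0, normexp called, in the order of the 3 comparisons, 15695, 13833 and 8814 probes. The changes of all 5 reversed genes were then positive, but bfsp1, gata2, enpep and prlr were not called. It then gave a median of 0.28 for neural crest at NF 16 against NF 2 and medians of -0.57 for neural crest and 1.09 for heart at NF 34 against NF 16. For the list medians the cause was not tested.

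With no filter on dim probes there were a median of 1.12 for neural crest at NF 16 against NF 2 and medians of -0.67 for neural crest and 0.32 for heart at NF 34 against NF 16, from more members tested. Only probes well above background on all 16 arrays (16318 tested) gave 10926 called and 4861 higher at NF 16 against NF 2, 9205 called and 3740 higher at NF 34 against NF 16, 5763 called and 1759 higher at NF 46 against NF 34 and 14413 probes that differ among the 4 stages. With 1 probe per named gene (4751 tested) there were 2975 called, 1601 higher and 1374 lower at NF 16 against NF 2, 2511 called, 1274 higher and 1237 lower at NF 34 against NF 16, 1642 called, 877 higher and 765 lower at NF 46 against NF 34 and 4182 probes that differ among the 4 stages. Specific probes alone (14204 tested) gave 8665 called, 5076 higher and 3589 lower at NF 16 against NF 2, 7188 called, 3736 higher and 3452 lower at NF 34 against NF 16, 4667 called, 2599 higher and 2068 lower at NF 46 against NF 34 and 12110 probes that differ among the 4 stages. Fewer probes were tested in these 3, but higher and lower did not shrink alike among probes on all 16 arrays or specific probes, and why was not tested. Specific probes turned the majority to higher at NF 34 against NF 16 and at NF 46 against NF 34, as did 1 probe per named gene.

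At least 2-fold as a further threshold gave 4415 lower at NF 34 against NF 16 and 5413 called and 2207 lower at NF 46 against NF 34. Limma's treat against 1.5-fold gave 5034 lower at NF 16 against NF 2, 7284 called, 4311 higher and 2973 lower at NF 34 against NF 16 and 3091 called, 1984 higher and 1107 lower at NF 46 against NF 34. Stricter thresholds are the cause.

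Camera with a preset correlation of 0.01 passed 21 list tests and fry, which asks if a list moves 1 way on balance, 41, while with an estimated correlation none passed. Median log2 changes of lists that passed both were oocyte and germ plasm -2.46, cell cycle and DNA replication -1.54, mesoderm and endoderm specification 4.92, neural plate patterning 3.11, Hox genes 3.67, skeletal muscle 1.27, extracellular matrix and cartilage 0.96 and cell stress 2.08 at NF 16 against NF 2. They were oocyte and germ plasm -2.63, mesoderm and endoderm specification -4.75, blood, globins and vasculature 2.13, liver and plasma proteins 1.31 and extracellular matrix and cartilage 0.69 (sign not kept) at NF 34 against NF 16. They were cell cycle and DNA replication -0.56, mesoderm and endoderm specification -0.61, neural plate patterning -0.996, Hox genes -0.69, neuronal differentiation and synapse 1.23, eye 1.13, thyroid and steroid hormone axes 0.74 and extracellular matrix and cartilage 1.13 at NF 46 against NF 34. Those that passed by fry only were neuronal differentiation and synapse 0.83, blood, globins and vasculature 0.48 (sign not kept), eye 0.42 (sign not kept), liver and plasma proteins 0.062 (sign not kept), pancreas, stomach and intestine 0.11 (sign not kept), epidermis, cement gland and hatching 0.60 (sign not kept), motile cilia 1.44, pronephric kidney 0.65 and thyroid and steroid hormone axes 0.70 (sign not kept) at NF 16 against NF 2. They were neural plate patterning 0.075 (sign not kept), neuronal differentiation and synapse 0.63 (sign not kept), skeletal muscle 1.19, pancreas, stomach and intestine 0.63 (sign not kept), epidermis, cement gland and hatching -0.36 (sign not kept), motile cilia -0.54 (sign not kept), thyroid and steroid hormone axes 1.37 (sign not kept) and oxidative phosphorylation 0.89 at NF 34 against NF 16. They were oocyte and germ plasm -0.51, pancreas, stomach and intestine 1.29 and motile cilia -0.38 at NF 46 against NF 34. For those marked, the sign turned under some alternative.

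Counted at 1 stage only, probes on at least 3 arrays of a stage and at most 1 other array numbered 66 at NF 2, 61 at NF 16, 7 at NF 34 and 607 at NF 46. With the flag of a positive and significant signal in place of well above background they numbered 0 at NF 2, 0 at NF 16, 0 at NF 34 and 12 at NF 46. With 1 array left out, numbers at 1 stage only ranged from 11 to 33 at NF 2, 18 to 28 at NF 16, 0 to 2 at NF 34 and 120 to 418 at NF 46. Leaving out 1 array, the neural crest median at NF 16 against NF 2 ranged from 0.50 (without NF 16 replicate 3) to 0.81 (without NF 16 replicate 4) and that of ribosomal proteins at NF 46 against NF 34 from -0.60 (without NF 46 replicate 1) to -0.47 (without NF 46 replicate 3).

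Replicate numbers do not pair the samples. Deviations from the stage means correlated at a mean r of 0.0168 over 24 pairs of arrays with the same number, 6 of them over 0.1. By best correlation, 1 of 16 arrays went with their own number, against 13 with their own slide. With the replicate block 16761, 13847 and 8808 probes were called for NF 16 against NF 2, NF 34 against NF 16 and NF 46 against NF 34, and 22849 were probes that differ among the 4 stages. The block ended 1 named call, of laptm5 at NF 46 against NF 34 (limma's adjusted p = 0.0731), and changed no list call.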

Other observations

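The tests of explanations and of gene families in this part were all chosen after the results were seen. Genes whose symbols share a stem were grouped into 33 families of at least 10 tested members. Their calls were set against all other named genes by Fisher's exact test, two-sided, in 198 tests. Those of the crygdl. family are not used here, since its probes can read the same transcripts and the test counts each gene as independent. Of the 18 genes with symbols starting with crygdl., gamma-crystallins of the lens, 16 were higher at NF 34 than at NF 16, against 26.6% of other genes. Higher and lower numbered 16 and 1 by quantile normalization, 16 and 2 centred on the median, 16 and 0 scaled to the spike-ins, 16 and 0 with normexp, 16 and 2 with its negative spots raised to 0 and 16 and 1 in the authors' values. At NF 16 against NF 2, 15 were lower, against 28.9%. There the numbers higher and lower were 1 and 16 by quantile normalization, 1 and 16 centred on the median, 1 and 15 scaled to the spike-ins, 0 and 0 with normexp, 1 and 15 with its negative spots raised to 0 and 1 and 15 in the authors' values. Median levels of these genes were -1.53, -1.15, 0.35 and -3.70 on NF 2 replicates 1 to 4 and -5.28, -4.90, -5.35 and -2.99 on NF 16 replicates 1 to 4. Without NF 2 replicates 2 and 3 and NF 16 replicate 4, 15 were lower, with a median log2 change of -2.47 against -3.07 with all arrays. NF 2 replicates 1 and 4, kept there, may hold a smaller trace of later-stage RNA too.

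All 18 crygdl. probes can bind other transcripts by the array's design. The 16 genes that were higher at NF 34 had an SD of 0.0407 log2 units across genes at NF 34. The 8 collagen genes that were higher had an SD of 2.90. The crystallin levels are consistent with probes that read the same transcripts, so that the number of lens genes that changed at either step stays open.

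The collagen family col, structural proteins of the matrix, had 8 of 11 members higher at NF 34 than at NF 16 (adjusted p = 0.0770, Fisher's exact test) and 7 higher at NF 46 than at NF 34 (adjusted p = 0.0711), with 4 and 4 higher with normexp and none lower under any of the 7 scalings at either step. The cytochrome P450 family cyp had 9 of 17 higher and 2 lower at NF 46 than at NF 34 (adjusted p = 0.0711, Fisher's exact test; 9 and 2 by quantile normalization, 9 and 2 centred on the median, 9 and 1 scaled to the spike-ins, 4 and 0 with normexp, 7 and 2 with its negative spots raised to 0 and 9 and 2 in the authors' values). These 3 tests did not pass.

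Signal relative to the spike-ins, control RNA added to the samples, differed among stages. The 75th percentile of an array minus the mean of its spike-ins was -5.57 ± 0.33 at NF 2, -5.61 ± 0.38 at NF 16, -4.67 ± 0.20 at NF 34 and -4.37 ± 0.21 at NF 46 (log2, SD, n = 4). A difference between slides is argued against, since NF 46 was higher than NF 2 within every slide, by at least 0.913. The 10 brightest spots held more of the signal at NF 2 (4.36% to 6.56%) than at NF 46 (3.17% to 3.31%), but abundant transcripts as the whole cause are argued against, since the share left for other spots differed by at most 0.0515 log2 units within a slide and the share of the 100 brightest, NF 2 minus NF 46, was -5.32 percentage points. Less spike-in RNA or label per sample at NF 46 cannot be told apart from more polyadenylated RNA per total RNA, as 58.6% of the difference lay in the spike-ins' own signal and the amount added to each sample is not given in the sources used here.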
